A study of Arabidopsis thaliana with 3 samples.

How the data were processed

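RNA of lateral nectaries was measured on 3 arrays, 2 of cwinv4-1 and 1 of wild-type. Per the labels' protocols, plants were 30 to 35 days old and grown under 16 h of light and 8 h of darkness, nectaries were collected 4 to 8 h after dawn into a preservative, and 500 ng of total RNA went through 1 round of amplification before biotin labelling. The series' design text names the samples as biological replicates. The title of replicate 1 of the mutant reads cwinv4-1a where its other labels read cwinv4-1; what the added letter means is not given, and the fit takes both mutant samples as replicates of one line. The deposited values are linear signal intensities per probe set and array. MAS5 made them, per the submitters' processing notes, with no version or target level given in the sources used here. The design text adds that other wild-type nectary arrays took part in the normalization; those arrays are not used here, and how they entered is not given. A cell without a value reads null, and its meaning is not given. Such probe sets had median signals of 115.9 to 131.2 on the other arrays, against 504.1 to 530.6 for all, and were kept as missing.

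The probe sets were named through GEO's platform annotation, matched by gene number to the RefSeq gene table of assembly TAIR10.1. Of the 14338 probe sets, 8037 had 1 gene name, 335 had several and 5966 were unnamed here. Of those with 1 name, 8000 matched 7936 loci, most of them named only by locus code. The files state no genome build, so no coordinates are given. Probe sets with several names were given none.

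Values were analysed as log2 of the deposited intensity, with no further normalization. Of 10334 probe sets with a signal on all 3 arrays, the 7750 whose mean log2 value was at or above the 25th percentile of such means were tested, 4019 of them with 1 gene name. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance on the mean), two-sided, cwinv4-1 minus wild-type, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The fit has 1 residual degree of freedom, from the mutant arrays, and the lone wild-type array is assumed to vary as they do. Moderation across probe sets added 15.4 prior degrees of freedom. A called probe set whose signals in 1 group all lay under the 25th percentile of their array has its fold given as a bound against that percentile.

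In 20 simulations on the means and spread of these 7750 probe sets, each with 200 changed ones, the test for cwinv4-1 against wild-type recovered 12.0% of those changed 2-fold and 82.5% of those changed 4-fold, and 14.7% of its calls were false, above the nominal rate. The prior degrees of freedom it estimated ran from 10.3 to infinite although 15.4 had been simulated. All 20 lists of 30 probe sets shifted by 0.5 on the log2 scale were found at an unadjusted camera p under 0.05, and 0 of 20 unshifted ones. Lists in the data were called on an adjusted p, and most were smaller. The simulations drew each probe set independently and with the same spread on all arrays. In the data the arrays differed in spread and members of some lists moved together, so these rates need not hold there.

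Gene lists were compared with camera of limma, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, separately for the lists fixed before the data were examined and for those added later. Each locus counted once, by its probe set with the highest mean, and lists with fewer than 3 tested members were not tested. That left 3 of the 29 fixed lists, since 15 had 1 or 2 tested members and 11 had none. The 24 added lists were written from the gene names present and from textbook loci. Of these, 18 did not pass, with adjusted p from 0.101 to 0.936. Medians were also set against 10000 random lists matched on mean signal.

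The genes named follow a rule fixed before the data were examined. It takes CWINV4 and up to 12 named genes per direction with both mutant arrays on the same side of wild-type. Those that passed come first, by size of change, then the next by the smaller of the 2 array ratios. It also takes up to 4 members of each list by smallest unadjusted p, and 14 further fixed genes, of which SWEET9 alone has a named probe set here. Counting CWINV4, 1 of the 15 single genes was thus measured. The rule was applied in the same way to the added lists that passed. Unnamed probe sets and other genes given by name were chosen after their values were seen.

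Alternatives tried were quantile normalization, median centring, a floor or a pseudocount at a signal of 222 (the 25th percentile of all values), no filter or a filter at the 50th percentile, eBayes without trend or with a robust prior, 1.5- and 3-fold in place of 2-fold, each mutant array alone, and for lists an estimated correlation, ranks, no trend, random lists and the mean of all probe sets of a locus. The estimated correlation rests on 1 residual degree of freedom, so hardly any list can pass under it. Added lists were also tested without the members that had passed alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.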

Results

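Gene expression was measured in the lateral nectaries of Arabidopsis thaliana (Columbia-0), the larger nectar glands of the flower, in plants carrying the cwinv4-1 allele and in wild-type plants. CWINV4 encodes a cell wall invertase, an enzyme that splits sucrose into glucose and fructose outside the cell, and the submitters describe the mutant as nectarless. The comparison therefore addresses which transcripts differ between glands that secrete nectar and glands that do not. There were 2 cwinv4-1 samples and 1 wild-type sample, each hybridised to its own 1-colour Affymetrix array. Each sample pooled about 250 to 300 hand-dissected nectaries from flowers at stages 14 to 15, when nectar is secreted. The table used here held 14338 probe sets besides 37 controls. A signal was given for 12441 of them on cwinv4-1 replicate 1, 11365 on cwinv4-1 replicate 2 and 12455 on the wild-type array. Median signals were 500.8, 549.8 and 507.8 in the same order. CWINV4 itself has no named probe set among those used here and is not analysed here, so the mutated gene could not serve as a check of the labels. Only 1 array stands for the wild-type, and the number of arrays limits the precision of every value below.

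The named genes that rose in cwinv4-1 nectaries included a proline dehydrogenase and 2 membrane transporters, and those that fell included a late embryogenesis abundant protein and a wound-responsive gene. AT5G38710, which encodes a proline dehydrogenase, rose 5.44-fold, from a signal of 532.5 in wild-type to 2696 and 3113 in the mutant arrays (log2 fold change 2.44, SE 0.37, limma adjusted p = 0.0156). OCT1, an organic cation transporter, rose 5.39-fold (log2 fold change 2.43, SE 0.41, limma adjusted p = 0.0198). AT2G39210, of the major facilitator family of membrane transporters, rose 4.16-fold and AT5G55050, a GDSL-type lipase, rose 4.86-fold. AT3G56360 rose 4.74-fold. AT1G66100, a thionin family gene, rose 3.78-fold (limma adjusted p = 0.0444) and AT3G47070 rose 3.72-fold (limma adjusted p = 0.0384), but in 8 other settings of the processing and the test these genes passed in only 3 and 4. The plastid gene rpl16, for a protein of the plastid ribosome, rose 6.94-fold (limma adjusted p = 0.0204, and 0.551 with a robust prior), by 1.97 on the log2 scale in replicate 1 and 3.62 in replicate 2, and plastid genes as a class stood apart on replicate 2, as given further on.

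AT4G10270, a wound-responsive family gene, was 6.80-fold lower in the mutant, with signals of 382 and 247.6 against 2092 in wild-type (log2 fold change -2.77, SE 0.42, limma adjusted p = 0.0156). LEA4-5, a late embryogenesis abundant protein that accumulates under water deficit, was 5.67-fold lower (log2 fold change -2.50, SE 0.41, limma adjusted p = 0.0188). AT4G18425 was 4.73-fold lower and AT3G60450, of the phosphoglycerate mutase family, was 3.91-fold lower. All 12 of these genes lay on the same side of the wild-type array in both mutant arrays, as the rule for naming them required.

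In total 33 of 7750 tested probe sets passed limma's moderated test at an adjusted p of 0.05, 17 higher and 16 lower in cwinv4-1. Each of the 33 was at least 2-fold apart from wild-type in both mutant arrays, which calling them on the mean of the same 2 ratios largely brings about. Only 8 of the higher and 4 of the lower ones carry a single gene name here. Among the unnamed, probe set 262883_at was at least 5.03-fold higher, a bound because its wild-type signal of 86.1 lay under the 25th percentile of that array. Probe set 252911_at was 6.26-fold higher, 259426_at was 8.20-fold lower, with a log2 difference of -2.07 in replicate 1 and a larger one in replicate 2, and 259831_at was 6.21-fold lower. At an unadjusted p of 0.05, 269 probe sets were higher and 234 lower. No probe set passed limma's test after quantile normalization, where 192 higher and 154 lower had an unadjusted p under 0.05, nor with low signals set to a floor, where the counts were 260 and 219. Median centring gave 95 calls.

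**Figure D1:**
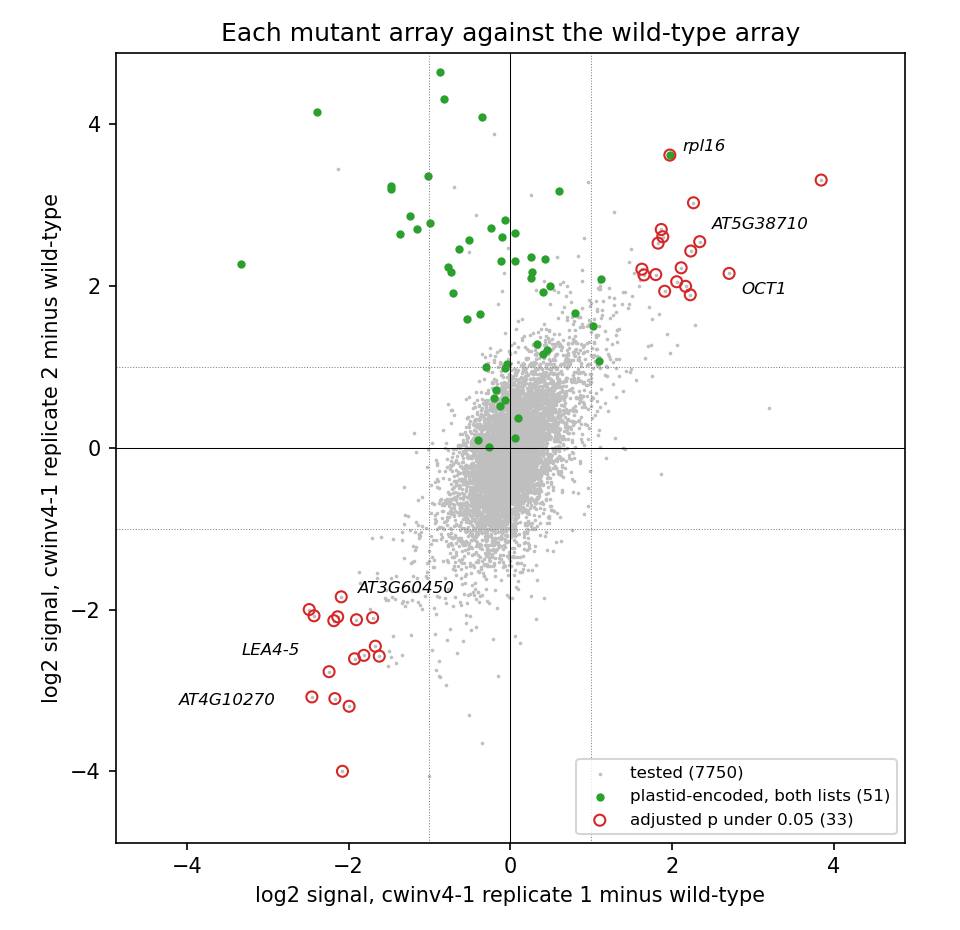
Log2 signal of cwinv4-1 replicate 1 (x axis) and of replicate 2 (y axis), each minus the wild-type array, for 7750 tested probe sets, with plastid-encoded genes in green and the 33 calls circled in red. Dotted lines mark 2-fold; the 33 calls lie beyond it in both arrays, while most of the 51 plastid-encoded genes are high on replicate 2 only.

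The next-ranked named genes did not pass the test. On the higher side these were ASPGB1, an asparaginase, at 3.36-fold (limma adjusted p = 0.053), AT4G09640 at 3.48-fold, TET16, a tetraspanin, at 3.59-fold and AT2G43670 at 3.31-fold. On the lower side AT2G23120, another late embryogenesis abundant family gene, had a signal of 16100 in wild-type and of 5678 and 2828 in the mutant, a 4.02-fold difference (limma adjusted p = 0.0792). AT4G14930 differed 3.69-fold, AT1G23710 3.64-fold, AT5G13240 3.40-fold and AT2G45820, a remorin, 3.13-fold. AT4G16670, AT2G21130 and AT1G26930 differed 3.09-, 3.08- and 2.92-fold.

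Counted by size alone, 100 probe sets were at least 2-fold higher and 77 at least 2-fold lower than wild-type in both mutant arrays, 52 and 32 of them with a single gene name. The single arrays differed in number. Replicate 1 had 134 higher and 100 lower by 2-fold, and replicate 2 had 382 and 490. Both ratios share the wild-type array, which alone makes them overlap. In 20 simulations of unchanged groups against 1 shared array, means were 64.8 higher (range 49 to 76) and 60.2 lower (range 48 to 86). The 77 lower lay within the simulated range and the 100 higher above it. These simulations gave all 3 arrays the spread between the mutant arrays, whose log2 difference had an SD of 0.65. Between replicate 1 and wild-type the SD was 0.44, so the simulated range cannot decide how much of either count is change. Independent lists of the observed sizes would share 6.60 and 6.32. The wild-type array cannot be split, so part of the overlap may come from the shared control. With cwinv4-1 replicate 2 put in the place of the lone array, 334 probe sets were 2-fold apart from both others, against 177 for the wild-type array and 19 for cwinv4-1 replicate 1. The limma calls of those splits were 19, 33 and 0, with 1548, 503 and 24 at an unadjusted p under 0.05.

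Genes of sugar metabolism, hormones, floral tissues and handling were followed in 29 lists fixed before the data were examined. Of their 386 loci, 24 were tested here and none passed limma's test over all probe sets, with 2 higher and 14 lower in both mutant arrays. Both ratios share the wild-type array, and of all 7750 tested probe sets 3419 were higher than wild-type on replicate 2. The split of all probe sets over both arrays was not counted, so no trend is read from these loci. SWEET9, the sucrose transporter of nectary secretion, had a signal of 16300 and 38100 in the mutant arrays and 19700 in wild-type. Its log2 fold change was 0.34 (SE 0.61, limma adjusted p = 1), and -0.07 after quantile normalization. SWEET1 was at a log2 difference of -0.18 in replicate 1 and 0.62 in replicate 2, and SWEET4 at -0.68 and -0.18. The list of sugar transporters did not pass (3 members, camera adjusted p = 0.885), and its medians were -0.27 in replicate 1 and 0.62 in replicate 2, so its direction turned with the array. The sucrose phosphatase gene SPP2 had a log2 fold change of 0.22 (-0.06 in replicate 1 and 0.50 in replicate 2), the starch synthesis gene APL3 of -0.08 (0.05 and -0.20) and PWD, a glucan dikinase of starch breakdown, of -0.68 (-0.41 and -0.96).

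Genes induced by sugar starvation were lower in cwinv4-1 by camera with a preset correlation, on 3 members. These are the only ones of the list's 20 loci with a named probe set here, so the rest of the class was not measured. Their median log2 fold change was -0.86, with medians of -0.91 in replicate 1 and -0.81 in replicate 2 (camera adjusted p = 0.0129, and adjusted p = 0.637 with an estimated correlation). ATG8E, an autophagy protein, had a log2 fold change of -1.05, MCCA, which takes part in leucine breakdown, of -0.86, and AKINBETA1, a subunit of the SnRK1 kinase, of -0.37. All 3 lay below wild-type in both mutant arrays, and 1 passed when adjusted over the list alone.

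Among the other fixed genes, GID1A, a gibberellin receptor, had a log2 fold change of -1.10 (limma adjusted p = 0.535) and CRT1b, a calreticulin of the endoplasmic reticulum, of 1.28 (limma adjusted p = 0.419), with log2 differences of -0.69 and 0.69 in replicate 1 and of -1.51 and 1.87 in replicate 2. JMT, a jasmonate methyltransferase, had a log2 difference of 0.06 in replicate 1 and -2.33 in replicate 2. OPCL1, of jasmonate synthesis, had a log2 fold change of -0.05 (-0.12 in replicate 1 and 0.01 in replicate 2), the auxin-conjugating WES1 of -0.66 (-0.24 and -1.09) and the flavonoid glycosyltransferase UGT78D2 of 0.60. Of genes marking other tissues or conditions, the pollen gene AT3G07820 was at -0.21 in replicate 1 and -2.36 in replicate 2, and the carpel regulator SPT at -0.19 and -1.17. The photosynthesis genes LHCB4.1 and RCA had log2 fold changes of -0.41 (-0.18 in replicate 1 and -0.64 in replicate 2) and -0.17, the clock gene GI of -0.92 (-0.36 in replicate 1 and -1.47 in replicate 2) and AUR1 of the cell cycle of 0.00 (-0.12 and 0.13), which is below 0 under quantile normalization and median centring. The 3 housekeeping genes had a median of -0.31, with medians of -0.05 in replicate 1 and -0.57 in replicate 2, and did not pass as a list (camera adjusted p = 0.876).

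A further 24 lists were written after it was seen which genes the table names and which probe sets passed the test, before any list value was computed, and 6 of them passed camera with a preset correlation. None of the 6 passed camera with an estimated correlation, where the lowest adjusted p of the 24 was 0.878. That setting rests on 1 residual degree of freedom, so hardly any list could pass it. Failing it does not count against a list, and the correlation between members stays unchecked. Genes of cytosolic ribosomal proteins were lower in cwinv4-1, with a median log2 fold change of -0.30 over 83 members and medians of -0.25 and -0.35 in replicates 1 and 2 (camera adjusted p = 0.000312, and adjusted p = 0.878 with an estimated correlation). Of the 83, 62 were lower and 4 higher in both mutant arrays, and none passed alone. The members named by the rule lay further down in replicate 2 than in replicate 1: AT5G47700 had log2 differences of -0.37 in replicate 1 and -1.49 in replicate 2, AT3G02190 of -0.47 and -1.23, AT5G27770 of -0.40 and -1.21 and AT4G39200 of -0.44 and -0.91. Proteasome subunit genes were also lower, with a median of -0.51 over 7 members, 6 of them lower in both arrays (camera adjusted p = 0.022, and adjusted p = 0.878 with an estimated correlation). In replicates 1 and 2, AT1G79210 was at -0.69 and -1.46, AT2G32730 at -0.88 and -0.69, RPN12a at -0.41 and -0.85 and AT5G23540 at -0.39 and -0.62.

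Cold and dehydration genes had a median log2 fold change of -0.88 over 7 members, with medians of -0.60 in replicate 1 and -1.16 in replicate 2 (camera adjusted p = 0.00131, and adjusted p = 0.878 with an estimated correlation). This call rested on LEA4-5, which had passed alone before the list was written: without it the adjusted p was 0.0709 and the median -0.62, and on ranks the whole list had an adjusted p of 0.135. COR15A, a cold-induced chloroplast protein, had a signal of 15300 in wild-type and of 8286 and 2170 in the mutant arrays, a log2 fold change of -1.85. COR27 was at -0.91 in replicate 1 and -2.75 in replicate 2, and ALDH7B4, a stress-induced aldehyde dehydrogenase, at -0.60 and -1.16. Of the 7, 5 were lower and 2 higher in both arrays. When adjusted over the list alone 3 passed as lower, among them LEA4-5, whose passing was known when the list was written.

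Plastid-encoded photosynthesis genes were higher by camera, with a median log2 fold change of 0.89 over 35 members (camera adjusted p = 1.61e-09, and adjusted p = 0.878 with an estimated correlation), but their medians were -0.11 in replicate 1 and 2.17 in replicate 2. Plastid genes for the ribosome and transcription likewise had a median of 0.87 over 16 members (camera adjusted p = 3.32e-07, and adjusted p = 0.878 with an estimated correlation), with -0.28 in replicate 1 and 2.28 in replicate 2. Without rpl16 the latter list had an adjusted p of 1.80e-05. Without replicate 2 both lists lay below wild-type. Only 12 of the 35 and 7 of the 16 members were higher in both arrays, and none was lower in both. Those higher in both included psbC, at log2 differences of 1.12 and 2.09, psaB, at 1.03 and 1.51, psbH, 2.12-fold over both, and rps19, at 0.80 and 1.67. The values of petA were 0.49 and 1.99, those of rpl36 0.60 and 3.17 and those of rps4 0.43 and 2.33. Photosynthesis genes of the nucleus were higher by less, with a median of 0.42 over 16 members and medians of 0.28 and 0.38 in replicates 1 and 2 (camera adjusted p = 0.0206, and adjusted p = 0.878 with an estimated correlation). Of the 16, 10 were higher in both arrays and 2, LHCB4.1 and RCA, lower in both. In replicates 1 and 2, PSAN was at 0.55 and 1.03, PSAE-1 at 0.87 and 0.58, SBPASE at 0.40 and 0.69 and NdhS at 0.30 and 0.67.

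**Figure D2:**
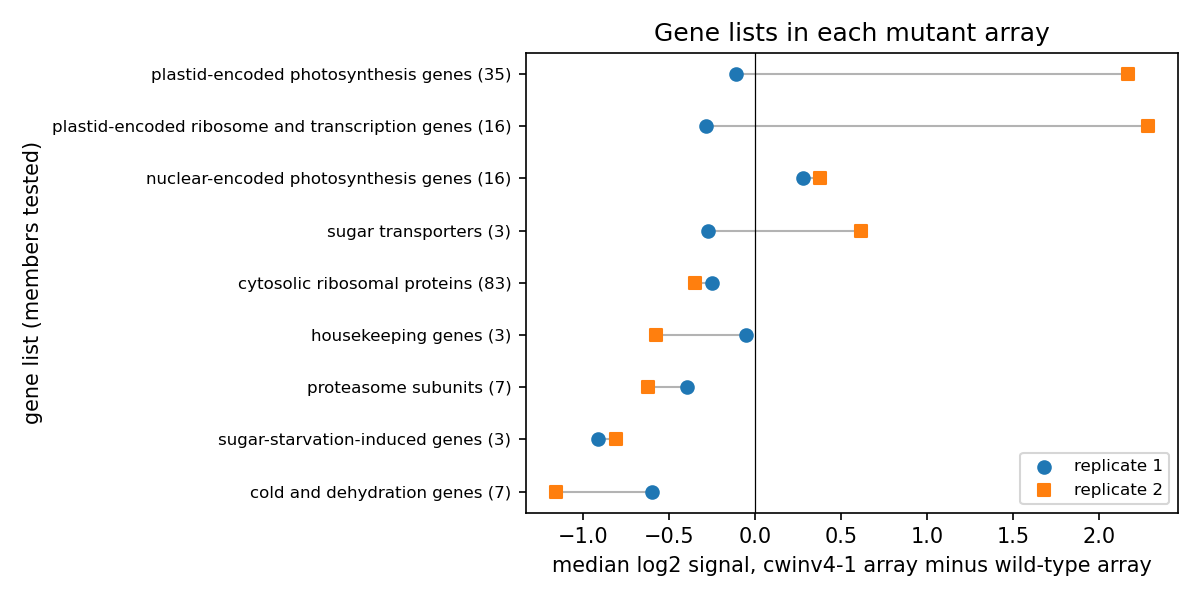
Median log2 signal of each gene list, cwinv4-1 array minus wild-type array, with replicate 1 as circles and replicate 2 as squares and the number of members tested in brackets. Both plastid-encoded lists lie above 2 in replicate 2 and below 0 in replicate 1. The ribosomal protein, proteasome, sugar-starvation, cold and housekeeping lists lie below 0 in both.

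The mutant arrays differed more from each other than replicate 1 did from wild-type. Over 10334 probe sets with a signal on all 3 arrays, the SD of the log2 difference was 0.65 between the mutant arrays, 0.44 between replicate 1 and wild-type and 0.73 between replicate 2 and wild-type. Replicate 2 also had the largest share of probe sets without a signal, 20.7% against 13.2% on replicate 1 and 13.1% on the wild-type array. The 3′ to 5′ signal ratio of 1 GAPDH control pair was 11.2 on replicate 2, 2.87 on replicate 1 and 4.82 on wild-type. For the other GAPDH pair the ratios were 2.436, 1.281 and 1.375 in the same order.

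**Figure D3:**
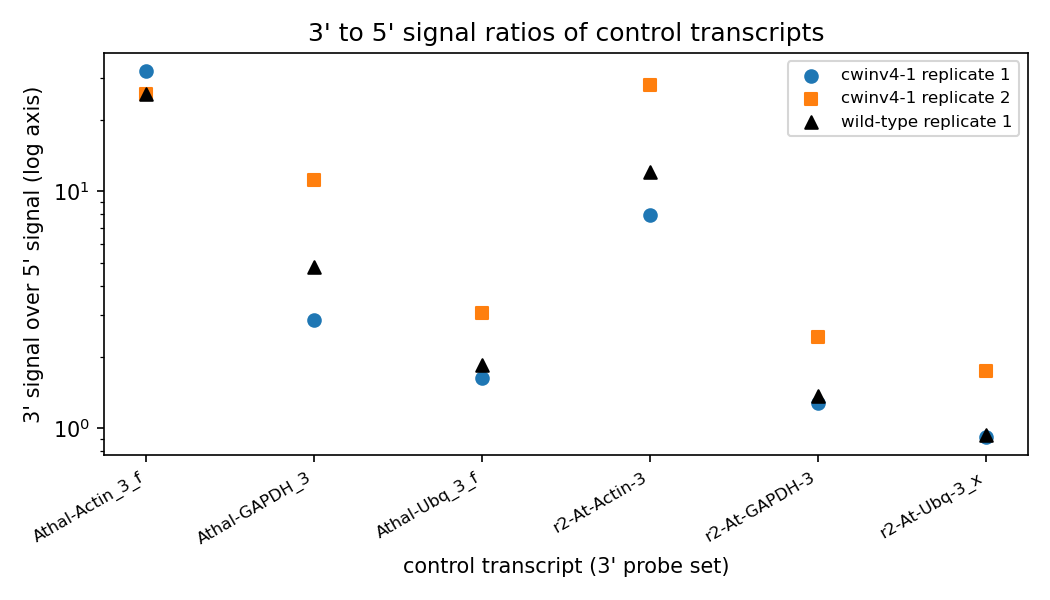
Signal of the 3′ probe set over that of the 5′ probe set (log axis) for 6 control pairs, of actin, GAPDH and ubiquitin, on each array. Replicate 2 of cwinv4-1 has the highest ratio in 5 of the 6 pairs; for the first actin pair its ratio is 25.8, as on the wild-type array.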

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

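The count of 3′ to 5′ ratios and the comparison of nuclear with plastid photosynthesis genes were chosen after their values were seen; the other tests of explanations given here were fixed before their results were seen.

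Control probe sets took no part in the comparison. The 3′ to 5′ signal ratio of 1 GAPDH pair was 11.17 on cwinv4-1 replicate 2, above the 4.82 of the wild-type array. The other GAPDH pair read 2.436 against 1.375. Replicate 2 departed from both other arrays more than they did from each other. Its 3′ to 5′ ratio was above both others in 5 of the 6 control pairs, so 3′-biased amplified RNA in cwinv4-1 replicate 2 is a candidate explanation. These pairs cover only actin, GAPDH and ubiquitin, so they are not independent of each other. The actin pairs disagreed, at 28.27 on replicate 2 against 7.977 (replicate 1) and 12.07 (wild-type), and at 25.78 against 32.18 and 25.81. A difference in signal spread predicted a fall to the wild-type array's count under quantile normalization. This was not seen, with 437 probe sets 2-fold apart on replicate 2 alone, against 167 on the wild-type array. Without that normalization replicate 2 had 334. Replicate 2 lacks the most signals, mostly at probe sets low on the other arrays, so fitting it to shared quantiles may itself shift it. Signal spread is therefore not decided. Gene length against its deviation gave a Spearman's rho across genes of -0.132 (0.0712 for replicate 1 and 0.105 for wild-type). This weak relation met the prediction, fixed beforehand, that longer genes read lower on replicate 2. The genes are not independent replicates, and only 51.0% of tested probe sets have a length. The check therefore speaks for those genes alone and does not decide the explanation. A difference between the plants behind the mutant samples was not tested.

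Plastid-encoded genes were high on replicate 2 and not, as a class, on replicate 1. More green tissue in that sample is argued against, since nuclear photosynthesis genes had a median log2 difference of 0.376 from wild-type there, against 2.17 for the plastid-encoded ones. Organelle transcripts mostly lack the long poly(A) tails that priming uses, and 8 mitochondrial-encoded probe sets were higher too, with a median of 1.15 over the mean of the other arrays and all 8 above it. A greater uptake of organelle RNA in replicate 2 may therefore account for the plastid values, as a hypothesis. An effect of the genotype on plastid transcripts stays open and untested, and rpl16, higher in both arrays, belongs to that class.

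The list of cytosolic ribosomal proteins was lower in both mutant arrays. The 3 housekeeping genes had a median log2 fold change of -0.31, near that of this list. Their medians were -0.05 in replicate 1 and -0.57 in replicate 2. All 83 ribosomal members have a length. Gene length is argued against as the whole cause, since 0 of 10000 random lists matched on mean signal and length had a median as low, the lowest being -0.18. Those lists were drawn from among the 51.0% of tested probe sets with a length. Array scaling predicted a rise of the median, which was -0.36 after quantile normalization. That setting also lowered the median of all tested probe sets, from -0.048 to -0.089. The list thus stayed below the tested probe sets as a whole, but a rise was hardly possible and array scaling is not decided. Median centring gave -0.352, but it lowers all log2 fold changes alike, so that value could not have risen and tests nothing here. A departure of the single wild-type sample stays open, as does the genotype, and neither was tested.

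Probe sets without a signal on every array were left out of the comparison, and 223 of them had a signal on both mutant arrays and none on the wild-type array, with a median of 101.4. A signal was missing on replicate 1 alone for 193 probe sets and on replicate 2 alone for 1430. These counts were set side by side after they were seen, and whether any of the 223 signals depends on the genotype was not tested.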

How the results depend on the processing

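The added lists were chosen after seeing the data. Against 17 probe sets higher and 16 lower, quantile normalization and a floor on low signals each gave 0 and 0, median centring 43 and 52, no filter 61 and 65 and a stricter filter 45 and 45. These counts went with limma's estimated prior degrees of freedom, 6.31, 11.8, infinite, 138 and 157 against 15.4, which 1 residual degree of freedom fixes poorly; no other cause was tested. Median centring and no filter kept all 33 calls. The stricter filter kept 26. It left AT4G10270 and AT4G18425 untested and lost none of the named calls that it tested. A pseudocount, no trend and a robust prior gave 33, 28 and 28 calls, with 29, 28 and 28 shared. The 12 named calls kept their direction in 94 values, and 30 of these lost the threshold. All 12 were lost under quantile normalization and the floor, AT1G66100 and AT3G47070 also with a pseudocount and without trend, and AT1G66100 and rpl16 also with a robust prior.

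Of 100 probe sets 2-fold higher and 77 lower in both arrays, a pseudocount left 38 and 48, which it lowers by construction, and the stricter filter left 51 lower, with fewer probe sets tested. At 1.5-fold the counts were 325 and 266, at 3-fold 23 and 19. Single mutant arrays gave 134 to 382 higher and 100 to 490 lower. Other settings stayed within 1.5 times.

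With an estimated correlation 0 lists passed, against 1 fixed list lower and 3 added lists in each direction. That setting rests on 1 residual degree of freedom and can hardly pass any list. The other settings kept these counts, except 2 added lists lower by ranks and without members that passed alone, the cold and dehydration list being lost in both. The plastid photosynthesis list ran from -0.11 to 2.17 and the plastid ribosome list from -0.28 to 2.28 with 1 mutant array, negative without cwinv4-1 replicate 2. The sugar transporters, at 0.22, were at 0.34 with no filter and ran from -0.27 to 0.62, negative without replicate 2, and the housekeeping genes from -0.57 to -0.052. After quantile normalization the sugar transporters and SWEET9 were at -0.075 and AUR1 at -0.060, and the cause was not tested. AUR1 was at -0.043 after median centring, which lowers all log2 fold changes alike (their median from -0.048 to -0.095). The cold and dehydration list, at -0.88, was at -1.35 with the stricter filter and -0.62 with no filter, which change the members tested, and ran from -1.16 to -0.60 with 1 mutant array. CWINV4 gave no value, camera takes no robust prior, and leaving out an array leaves no test. No paired analysis was possible because the groups share 1 replicate number. Lists under 3 tested members and probe sets of low signal limit what could be seen.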

Other observations

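Probe sets with a signal on the wild-type array alone numbered 498, against 454 on cwinv4-1 replicate 1 alone and 615 on replicate 2 alone. The highest named ones on wild-type alone were AT5G17850, with a signal of 587.7, PUB19, a ubiquitin ligase induced by drought, with 466.8, and AT3G02480, of the late embryogenesis abundant family, with 423.5. HAT2, an auxin-induced homeodomain gene, had 412.2. With a signal on both mutant arrays and none on wild-type, AT3G13760 had 438.5 and 1073, AT1G27430 had 680.6 and 558.6, and SBE2.2, a starch branching enzyme, had 291 and 528.6. These genes were chosen after their values were seen, and no test was made of them.

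Branched-chain amino acid breakdown genes had a median log2 fold change of -0.30 over 7 members, 6 of them lower in both mutant arrays (camera adjusted p = 0.113), and genes of the TRICHOME BIREFRINGENCE-LIKE family, of cell wall acetylation, had a median of 0.52 over 4 members (camera adjusted p = 0.101). Both lists missed the threshold. The 18 spike-in probe sets had a median ratio of 1.67 on cwinv4-1 replicate 2 over wild-type and of 0.732 on replicate 1 over wild-type.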
